A study of Homo sapiens with 6 samples.

How the data were processed

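The series holds 6 RNA-seq libraries of JHH-4 cells, 3 from control cells and 3 from cells overexpressing hsa-miR-372-3p from a plasmid. Per the labels' protocols, total RNA was isolated on columns and 1 µg was made into libraries with a NEBNext Ultra RNA kit, which does not mark strand; the selection of RNA is not given in the sources used here. Samples were grouped, and replicates numbered, by their titles. The series calls the replicates technical. One deposited table was used, and its columns name the group and replicate; 0 per-sample columns were left without a sample.

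The authors' table gives, per the file headers, read counts and FPKM for each library and a p-value and log2 fold change for the comparison. The submitters' processing notes name GRCh38 (hg38), HISAT2 2.0.4, StringTie 2.2.1 and DESeq2 1.38.3, without saying which step each served; the annotation release and the way reads were counted are not given in the sources used here. The deposited counts are whole numbers that were not normalized. The deposited FPKM values, scaled by the authors to gene length and depth, were not tested, because the counts suit a count model. The deposited p-value matched the unadjusted p of a DESeq2 fit of the same counts (median ratio 1), so it appears not to be adjusted for multiple tests. In the authors' deposited table, 7335 named genes had a p under 0.05, and 745 of them an absolute log2 fold change of at least 1. Across genes, which are not independent replicates, the authors' log2 fold changes correlated with those computed here at 0.99994.

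The table has 14006 rows. Of these, 12396 carry an Ensembl gene ID and were analysed; the other 1610 are loci assembled from the reads, with no gene name, and were kept out of library sizes and tests. Those loci held 3.18, 2.88 and 3.63% of counts in control replicates 1 to 3 and 2.64, 2.74 and 2.69% in overexpression replicates 1 to 3. No row has fewer than 208 counts over the 6 libraries, so genes of low expression are not analysed here. The symbols of 9 genes had turned into dates and were replaced through their IDs; 12370 IDs had a symbol in a table of current names. All 12396 IDs were found in GENCODE 29 (GRCh38), which gave positions, and 12391 are protein-coding there. Counts of near-identical paralogs, of overlapping genes and of read-through transcripts are uncertain, because the counting is not described and the kit does not mark strand.

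Total counts ran from 48325676 to 61699567 per library, deeper in overexpression than in control, and filterByExpr removed 0 genes. Counts were tested with edgeR 4.0.16 in R 4.3.3 (TMM factors, quasi-likelihood F-test, 2 groups, no block), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Standard errors and 95% confidence intervals of log2 fold changes come from that fit. CPM values scale the counts to 1000000 reads of the TMM-scaled library size. The common biological coefficient of variation was 0.0796. Every pair of replicates within a group differed by more than counting noise (chi-square per degree of freedom 6.86 to 38.6), so no library looks like another deposited again. This does not show that the replicates were separate cultures; n = 3 counts libraries.

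Tested on simulated data made from the means and library sizes of these 12396 genes, with 200 genes changed, the fit for overexpression against control recovered 42% of genes changed 1.25-fold, 76% at 1.5-fold, 94% at 2-fold and 100% at 3-fold, with 14 false calls. Far more genes passed in the data (6761), which moves the cut-off on p that the adjustment sets. The rates and false calls of the simulation therefore need not hold for the data.

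Before the data were examined, 22 gene lists, the rule for named genes, the tests and most alternatives were fixed. Lists were tested with camera in limma 3.58.1 on voom values with a preset correlation of 0.01 between genes, adjusted over the 22 lists, beside camera with an estimated correlation and fry. Named genes were CPT1A and ACSL4; the 5 genes with the highest and the 5 with the lowest log2 fold change that passed the threshold, had a mean of at least 2 CPM and did not overlap between groups; from each list the members past the threshold with the largest absolute change, up to 3 for lists of lipid metabolism and published targets and up to 2 for the others; and the 5 lowest genes with an 8mer site and a mean of at least 2 CPM. Some genes that this rule names are not reported here. Other members named with a list were chosen after their values were seen.

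Sites of miR-372-3p were sought in the 3′ UTR of each gene's protein-coding transcript with the longest 3′ UTR in GENCODE 29, for the 12188 genes whose 3′ UTR is at least 50 nt. A gene was classed by its best match: 8mer (AGCACTTA), 7mer-m8 (AGCACTT), 7mer-A1 (GCACTTA), 6mer (GCACTT) or none. Classes were tested by camera and by 100000 permutations within 20 bins of 3′ UTR length. All 7-mers in at least 100 genes were ranked after removing the mean of 20 length bins, each with 10 GC bins. The isoforms and 3′ ends that JHH-4 cells use were not analysed here.

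Alternatives were RLE and upper-quartile factors, DESeq2 1.42.0, limma-voom, no filter, a minimum mean of 5 CPM, leaving out each library, the replicate number as a block, other 3′ UTR choices, and, chosen after seeing the data, including the assembled loci and leaving out genes with the Alu form of the site. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 served for sites and plots.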

Results

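RNA-seq compared JHH-4 cells, a human hepatocellular carcinoma line, carrying a control with JHH-4 cells that overexpressed hsa-miR-372-3p from a plasmid coding for its primary transcript. miR-372-3p is a microRNA of the family of miR-302, miR-372 and miR-373, which pairs with short sites in the 3′ UTRs of messenger RNAs and lowers their level or translation. Each group held 3 libraries, which the series describes as technical replicates, so the p-values below measure only the spread between these libraries. Total counts were 48391596, 48325676 and 49693205 in control replicates 1 to 3, and 61699567, 52511378 and 57385849 in overexpression replicates 1 to 3. The groups separated along the first principal component, which held 72.5% of the variance. Control replicate 3 stood apart from the other 2 controls on the second component (10.2% of the variance), at −22.01 against 14.45 and 7.27.

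The comparison asked how miR-372-3p overexpression changed expression, with fatty acid metabolism and the genes CPT1A and ACSL4 named in the series title. Both genes fell. CPT1A, which makes the acylcarnitines that carry long-chain fatty acids into mitochondria, dropped 2.91-fold, and ACSL4, which joins polyunsaturated fatty acids to coenzyme A, dropped 1.85-fold. Genes on the lists of mitochondrial fatty acid oxidation, of fatty acid uptake and acyl-CoA synthetases, and of fatty acid synthesis fell more often than they rose. So did genes of the S, G2 and M phases and interferon-stimulated genes. With an estimated correlation between genes, 0 of the 22 gene lists passed as a whole. The change reached a large part of the transcriptome: of 12396 genes tested, 3323 rose and 3438 fell, while 350 rose and 397 fell by at least 2-fold.

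CPT1A (ENSG00000110090, chromosome 11, 68754620 to 68844410, minus strand, GRCh38) had a normalised count of 64.6 ± 3.05 CPM (SD, n = 3) in control and 22.2 ± 1.44 (SD, n = 3) in overexpressing cells. Its counts were 3197, 2909 and 3073 in the controls and 1344, 1042 and 1315 in the overexpression libraries. The log2 fold change was −1.54 with a standard error of 0.060 and a 95% confidence interval of −1.68 to −1.41 (edgeR adjusted p = 5.62e-08). The 3′ UTR of its transcript with the longest 3′ UTR (2755 nt, 68754889 to 68757643) held 2 copies of AGCACTT, the match to nucleotides 2 to 8 of miR-372-3p. One lay at 68755328 to 68755334. The other, at 68755670 to 68755676, lay in the sequence AGCACTTTGGGAGG, a form that recurs in Alu repeats. Such matches are common: 3111 of the 12188 genes searched for sites held AGCACTT. Of the genes with AGCACTT as their best match, 29.7% fell and 27.1% rose, against 26.2% and 26.7% of genes with no match.

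ACSL4 (ENSG00000068366, chromosome X, 109624244 to 109733403, minus strand, GRCh38) had 112 ± 2.90 CPM (SD, n = 3) in control and 60.5 ± 3.73 (SD, n = 3) in overexpressing cells. The log2 fold change was −0.89 with a standard error of 0.053 and a 95% confidence interval of −1.01 to −0.77 (edgeR adjusted p = 6.89e-07). Its counts were 5114, 5298 and 5542 in the controls and 3847, 2866 and 3401 in the overexpression libraries. The longest annotated 3′ UTR of ACSL4 (2692 nt, 109641337 to 109644028) held no AGCACTT and a single 6-base match, GCACTT, at 109642630 to 109642635. In the authors' deposited table the log2 fold change was −1.54 for CPT1A and −0.89 for ACSL4. Transcripts of the miR-371 to miR-373 locus, which would check the overexpression itself, were not analysed here.

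**Figure D1:**
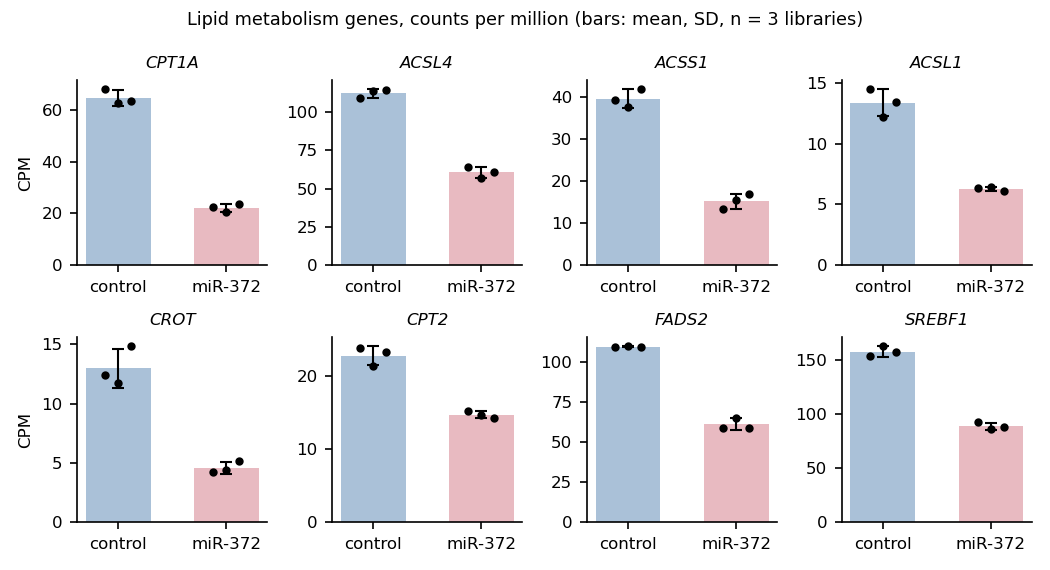
CPM (y axis, from 0) of 8 lipid metabolism genes in the 3 control and 3 overexpression libraries; bars are means, error bars SDs and points single libraries. All 3 overexpression libraries lie below all 3 controls for each gene, with CPT1A at 64.6 against 22.2 CPM and ACSL4 at 112 against 60.5 CPM.

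Log2 fold changes of the genes below are of overexpression over control, each with its standard error, from 3 libraries a group. Of 26 measured genes of mitochondrial fatty acid oxidation, 14 fell, 1 rose and 11 did not pass the test, and adjusted over the list alone the counts were also 14 and 1. Besides CPT1A, these were led by CPT2 (−0.63 ± 0.070), which turns acylcarnitines back into acyl-CoA inside mitochondria, and ETFDH (−0.59 ± 0.071), which passes electrons from acyl-CoA dehydrogenases to ubiquinone. The list was lower as a set (camera adjusted p = 0.00637), with adjusted p = 0.386 with an estimated correlation. Of 23 genes on the list of fatty acid uptake and acyl-CoA synthetases, 13 fell and 3 rose, also adjusted over the list alone. That list also holds acyl-CoA thioesterases, such as ACOT9 and ACOT13, and the acyl-CoA-binding proteins ACBD3 and DBI. The acetyl-CoA synthetase ACSS1 (−1.38 ± 0.086), the acyl-CoA synthetase ACSL1 (−1.09 ± 0.096) and ACSL4 fell most. The set test gave an adjusted p of 0.00637, and an adjusted p = 0.22 with an estimated correlation. Of 27 genes of fatty acid synthesis, elongation and desaturation, 15 fell and 4 rose, and adjusted over the list alone 15 fell and 4 rose (camera adjusted p = 0.00637; adjusted p = 0.22 with an estimated correlation). The desaturase FADS2 (−0.84 ± 0.050), the transcription factor SREBF1 (−0.83 ± 0.043) and the elongase ELOVL7 (−0.80 ± 0.058) fell; FASN and ACACA were among the 4 that rose.

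Cholesterol genes went both ways. Of 25 measured, 7 rose and 11 fell, and adjusted over the list alone 8 rose and 11 fell; the set as a whole did not pass (camera adjusted p = 0.712). HMGCS1 (0.67 ± 0.068), an early enzyme of the mevalonate pathway, rose. Among 23 genes of triacylglycerol synthesis, lipid droplets and lipolysis, 5 rose and 9 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.501). G0S2, an inhibitor of the lipase ATGL, rose (1.12 ± 0.169), while FITM2 (−1.12 ± 0.084), needed for lipid droplet formation, and the phosphatidate phosphatase LPIN1 (−0.88 ± 0.045) fell. In the list of peroxisomal oxidation and PPARA targets, 7 of 23 fell and 2 rose, also adjusted over the list alone (camera adjusted p = 0.226). CROT, the peroxisomal carnitine octanoyltransferase, fell 2.82-fold (−1.49 ± 0.126), ACOX2 fell 2.12-fold (−1.09 ± 0.159), and the nuclear receptor gene PPARA fell 1.41-fold (−0.49 ± 0.086). The 3′ UTR of CROT held 2 copies of AGCACTTA, the 8-base match, at 87398662 to 87398669 and 87399623 to 87399630 of chromosome 7.

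Of 22 genes of ferroptosis and glutathione defence, 7 rose and 10 fell, also adjusted over the list alone (camera adjusted p = 0.333). LPCAT3 (−0.78 ± 0.090), which places polyunsaturated fatty acids into phospholipids, and the haem oxygenase HMOX1 (−0.77 ± 0.039) fell most. Of 20 glycolysis genes, 6 rose and 12 fell, also adjusted over the list alone, and the set did not pass (camera adjusted p = 0.0946), although it did without control replicate 2 (adjusted p = 0.0448). With the estimated correlation of 0.202, camera over all 6 libraries gave an adjusted p of 0.523. The lactate transporter SLC16A3 rose (0.90 ± 0.151) and PFKFB4 fell (−0.88 ± 0.062).

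Published targets of the family of miR-302, miR-372 and miR-373 were lower as a group. Of 22 measured, 13 fell and 4 rose, also adjusted over the list alone (camera adjusted p = 0.00637; adjusted p = 0.248 with an estimated correlation). MICA, a ligand of the natural killer cell receptor NKG2D, fell 3.88-fold (−1.96 ± 0.064), and DAZAP2 fell 2.37-fold (−1.24 ± 0.040). TP53INP1, listed both here and among p53 targets, rose 4.13-fold (2.05 ± 0.123). Its 3′ UTR held AGCACTT, as did that of DAZAP2, which fell. Of 20 genes of the small RNA machinery, 8 rose and 3 fell, also adjusted over the list alone (camera adjusted p = 0.226). LIN28A, an RNA-binding protein that blocks let-7 processing, rose (3.75 ± 0.517), from 0.0975 ± 0.0865 to 1.36 ± 0.204 CPM (SD, n = 3), with 14 counts in the 3 control libraries together (log2 fold change 4.35 without control replicate 3). AGO4, an Argonaute protein, rose 1.58-fold (0.66 ± 0.092).

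Proliferation genes fell by small amounts. Of 28 genes of the G2 and M phases, 20 fell and 1 rose, also adjusted over the list alone (camera adjusted p = 0.000802; adjusted p = 0.22 with an estimated correlation), led by HMMR (−0.62 ± 0.057) and NUSAP1 (−0.51 ± 0.050), both of which bind mitotic spindle microtubules. Of 28 S phase genes, 15 fell and 4 rose, also adjusted over the list alone (camera adjusted p = 0.00984; adjusted p = 0.248 with an estimated correlation). RRM2, a subunit of ribonucleotide reductase, fell 1.66-fold (−0.73 ± 0.033). Replication-dependent histone genes, whose main transcripts lack a poly(A) tail, went the other way: 6 of 9 measured rose and none fell, also adjusted over the list alone (camera adjusted p = 0.00637; adjusted p = 0.248 with an estimated correlation). HIST2H4A (1.51 ± 0.297) and HIST1H2BD (1.24 ± 0.148) rose most, at 8.92 ± 0.724 and 12.9 ± 1.11 CPM (SD, n = 3) in overexpressing cells; histone genes have near-identical copies, so their counts are uncertain. Of 27 p53 targets, 10 rose and 7 fell, and adjusted over the list alone 11 rose and 8 fell (camera adjusted p = 0.22). The death receptor FAS fell 5.16-fold (−2.37 ± 0.183). Of 27 genes of the unfolded protein and integrated stress response, 9 rose and 7 fell, also adjusted over the list alone (camera adjusted p = 0.712), with CHAC1 (0.95 ± 0.099) and ATF3 (0.63 ± 0.129) rising most.

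Interferon-stimulated genes were lower. Of 28 measured, 18 fell and 3 rose, also adjusted over the list alone (camera adjusted p = 0.00278; adjusted p = 0.22 with an estimated correlation). XAF1, a promoter of apoptosis, fell 17.3-fold (−4.11 ± 0.390), from 2.01 ± 0.507 to 0.114 ± 0.0715 CPM (SD, n = 3; log2 fold change −4.75 without overexpression replicate 3), and OASL fell 5.91-fold (−2.56 ± 0.283). Of 22 NF-kB and immediate early genes, 7 rose and 9 fell, also adjusted over the list alone (camera adjusted p = 0.625). The chemokine CCL2 fell (−2.30 ± 0.301) and FOSB rose (1.69 ± 0.240).

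YAP/TAZ targets rose in 15 of 22 cases and fell in 4, also adjusted over the list alone (camera adjusted p = 0.00399; adjusted p = 0.248 with an estimated correlation). ANKRD1 rose 3.79-fold (1.92 ± 0.041), from 297 ± 13.9 to 1124 ± 10.2 CPM (SD, n = 3), and CTGF (now CCN2), a secreted matricellular protein, rose 2.65-fold (1.40 ± 0.051). Of 26 epithelial-mesenchymal and TGF-beta genes, 14 rose and 5 fell, also adjusted over the list alone (camera adjusted p = 0.0182; adjusted p = 0.248 with an estimated correlation). The largest rise among them was that of KRT18 (1.31 ± 0.052), a keratin of simple epithelia; its partner KRT8 and KRT19 also rose. LOX, which crosslinks collagen, rose as well (1.12 ± 0.135).

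Hepatocyte genes split. Of 12 measured, 5 rose and 6 fell, also adjusted over the list alone, and the set did not pass (camera adjusted p = 0.729). SERPINA1, coding for alpha-1-antitrypsin, fell 5.09-fold (−2.35 ± 0.169), while the 3 fibrinogen chain genes FGA, FGB and FGG rose. Of 13 mitochondrially encoded genes, 1 rose and none fell, and adjusted over the list alone none passed (camera adjusted p = 0.625, and 0.0282 without control replicate 2); the median log2 fold change was −0.026 and the mean 0.057. That gene was MT-ND4 (0.36 ± 0.109, adjusted p = 0.0176), whose adjusted p was 0.0538 without control replicate 1 and 0.0685 without overexpression replicate 2. The correlation estimated between the mitochondrially encoded genes was 0.946, far from the preset 0.01, and camera with it gave an adjusted p of 0.849. The share of counts in mitochondrial genes was 5.60, 6.55 and 4.62% in the controls and 5.91, 6.30 and 5.93% in the overexpression libraries. Of 7 measured markers of blood, endothelial and stromal cells, 2 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.625; median −0.013, mean 0.53). COL1A1 rose 13.2-fold (3.72 ± 0.197), from 4.84 ± 1.98 to 64.0 ± 3.63 CPM (SD, n = 3), and PDGFRB rose 2.23-fold (1.16 ± 0.079).

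**Figure D2:**
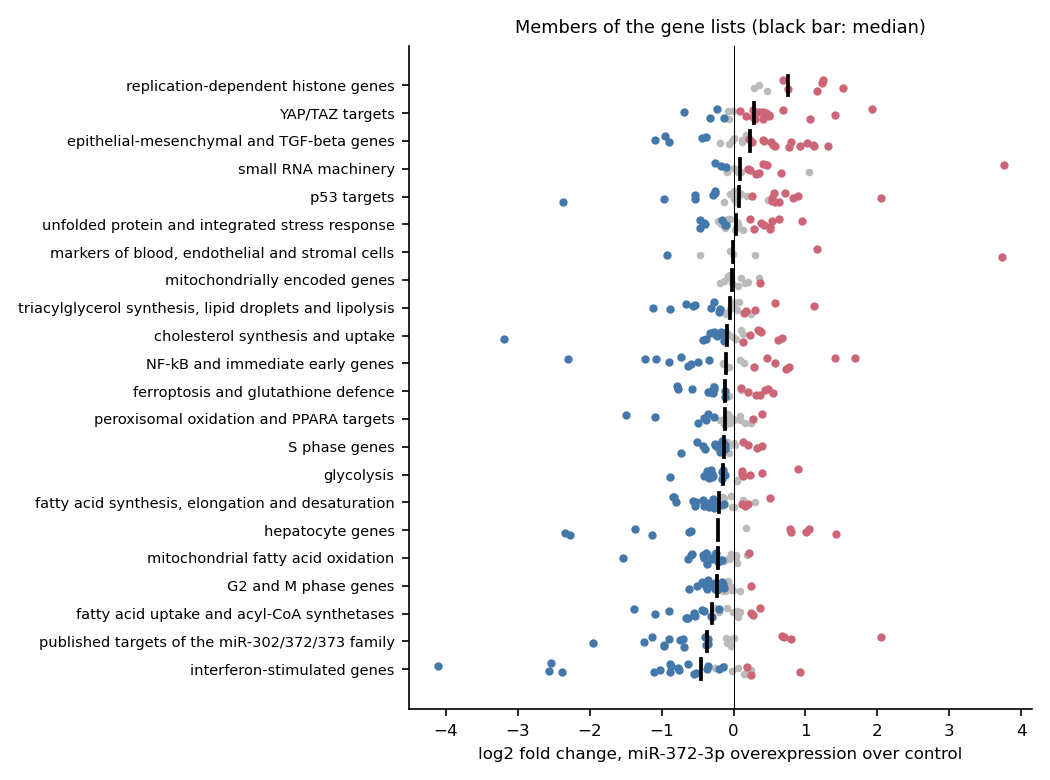
Log2 fold change (x axis, overexpression over control) of each measured member of the 22 gene lists (y axis); red points rose and blue points fell at an adjusted p of 0.05, grey points did not pass, and black bars are list medians. The medians run from −0.447 for interferon-stimulated genes to 0.757 for replication-dependent histone genes.

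Among genes with a mean of at least 2 CPM, those that rose most were outside these lists. TNFSF18, a ligand of the TNF family, rose most (6.05 ± 0.489), from 0.0829 ± 0.109 to 5.75 ± 0.564 CPM (SD, n = 3), with 2, 0 and 10 counts in the controls; without control replicate 3 the log2 fold change was 7.92, so its size is uncertain. TAGLN, an actin-binding protein of smooth muscle, rose 25.5-fold (4.67 ± 0.152), from 1.47 ± 0.445 to 37.6 ± 1.58 CPM (SD, n = 3). GGT5 (4.36 ± 0.181), KISS1 (4.30 ± 0.217) and the keratin gene KRT81 (4.24 ± 0.059) followed; KRT81 has close paralogs and reached 247 ± 5.97 CPM (SD, n = 3). Genes that fell most included PRODH2 (−4.88 ± 0.202), an enzyme of hydroxyproline breakdown, CLVS1 (−3.88 ± 0.186), HSD17B2 (−3.66 ± 0.238), a steroid dehydrogenase, and HLA-DRA (−3.66 ± 0.099), the alpha chain of the MHC class II molecule HLA-DR. HLA-DRA went from 43.7 ± 2.21 to 3.46 ± 0.466 CPM (SD, n = 3).

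Most changes were small: 4831 of the 6761 changed genes differed by less than 1.5-fold, and the median absolute log2 fold change among changed genes was 0.375. In 7708 genes (62.2%) all 3 libraries of one group lay above all 3 of the other, against 10% by chance. Among the 22 lists, 7 were lower and 3 higher by camera with a preset correlation of 0.01, and 0 held with an estimated correlation, where 4 had an unadjusted p under 0.05; fry, which asks only whether a list's genes move one way, gave 17. The estimated correlation was −0.00401 for interferon-stimulated genes and 0.00131 for fatty acid synthesis, elongation and desaturation, both under the preset 0.01. In the other lists that passed with the preset it ran from 0.0102 to 0.168. For the lists under 0.01, a higher correlation is therefore not what removed the call. With a minimum mean of 5 CPM, 179 genes rose and 232 fell by at least 2-fold.

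Genes whose 3′ UTR held the 8-base match to miR-372-3p were lower than genes with no match. Of 493 genes with AGCACTTA, 221 (44.8%) fell and 104 (21.1%) rose, against 26.2% and 26.7% of 7243 genes without a 6-base match. Their median log2 fold change was −0.129, against 0.00837 for genes with no match, a difference of −0.138 (camera adjusted p = 0.00147; adjusted p = 0.0379 with an estimated correlation). Among genes with 3′ UTRs of 200 to 3000 nt alone, the difference was −0.278 (camera adjusted p = 4.26e-07). Over all lengths it was −0.157 beyond that of random genes of matched 3′ UTR length (permutation within 20 length bins, two-sided p = 1e-05, the smallest that 100000 permutations can give). For the 2618 genes whose best match was AGCACTT, the difference was −0.0195 and did not pass in camera (adjusted p = 0.779; −0.0122 without control replicate 2, −0.0046 without overexpression replicate 2, and −0.0495 for 3′ UTRs of 200 to 3000 nt), while the length-matched difference was −0.0475 (permutation, two-sided p = 1e-05, the smallest possible); this permutation treats genes as independent. Together, the 8mer and 7mer-m8 classes gave a length-matched difference of −0.0593 (permutation, two-sided p = 1e-05). In 39.3% of the genes with AGCACTT as their best match, the 3′ UTR held the Alu form of the site. Genes with GCACTTA as the best match (442 genes, −0.0152) or only GCACTT (1392 genes, 0.00772) did not pass either (camera adjusted p = 0.779 for both).

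Among genes with AGCACTTA, the urea transporter gene SLC14A1 fell most (−2.84 ± 0.110), with the site at 45752445 to 45752452 of chromosome 18. SEMA5A fell 5.59-fold (−2.48 ± 0.288), with the site at 9036180 to 9036187 of chromosome 5. HFE, a regulator of iron uptake, fell 5.00-fold (−2.32 ± 0.131), with the site at 26095080 to 26095087 of chromosome 6. MICA carried the site at 31415243 to 31415250 of the same chromosome. HSPA4L, a chaperone of the HSP110 family, fell 3.79-fold (−1.92 ± 0.061) and carried 3 copies, the first at 127833872 to 127833879 of chromosome 4. All of these sites lay in 3′ UTR exons of GENCODE 29 transcripts.

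**Figure D3:**
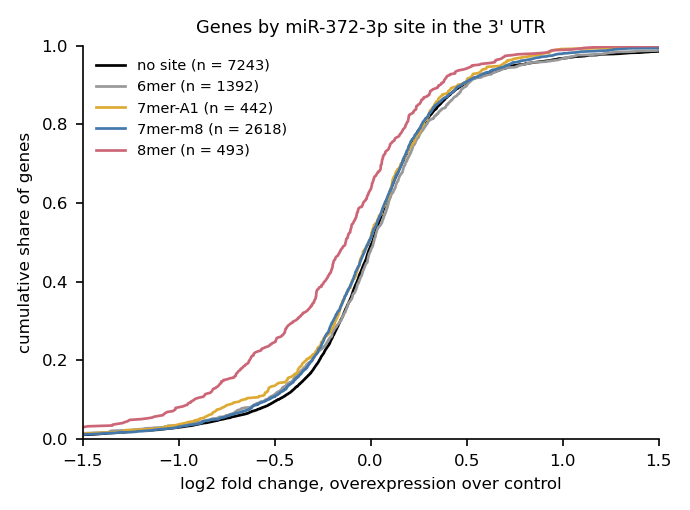
Cumulative share of genes (y axis) by log2 fold change (x axis, overexpression over control) for genes without a match to miR-372-3p and for genes grouped by their best match in the 3′ UTR; numbers of genes stand in the legend. The curve of the 493 genes with the 8-base match lies left of that of the 7243 genes without a match, with medians of −0.129 and 0.00837.

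Over all 15926 7-mers found in the 3′ UTRs of at least 100 genes, AGCACTT had the 70th lowest difference of mean log2 fold change after removal of the trend on 3′ UTR length and GC content (−0.0745 ± 0.0108, SE across genes, which are not independent replicates). GCACTTA, the end of the 8-base match, ranked 4 from the lowest (−0.120). All 493 genes with AGCACTTA hold both of these 7-mers, so both differences include that of the 8mer. Genes with GCACTTA as their best match had a median difference of −0.0152 from genes with no match (camera adjusted p = 0.779). These ranks take no account of how many genes hold a 7-mer, and means over fewer genes vary more. The lowest, GCCGATC (−0.148), was in 111 genes, against 3111 for AGCACTT and 1174 for GCACTTA. ATTTGAG, the match to the other arm, miR-372-5p, had a difference of 0.0081 and rank 10443.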

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

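The values here come from rows that no comparison of the report uses, the loci assembled from the reads without a gene name, and they were examined after the other results were seen. Of 1610 such loci, 91 were higher and 83 lower in overexpressing cells by at least 2-fold at an edgeR adjusted p of 0.05; in all, 369 were higher and 316 lower. One locus had 0 counts in all 3 control libraries and 203, 73 and 146 counts in the overexpression libraries, 422 in sum. The table gives no positions for these loci, so whether this one holds plasmid sequence, or any gene, was not analysed here.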

How the results depend on the processing

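Alternatives were planned, except the assembled loci and the Alu form, which were chosen after seeing the data. CPT1A (−1.585 to −1.496) and ACSL4 (−0.935 to −0.848) stayed below 0 and past the threshold under all alternatives run. The numbers of genes that rose (2800 to 3546) and fell (2961 to 3553) stayed within 1.5 times the reported counts. A minimum mean of 5 CPM left 10683 genes and lowered the genes changed at least 2-fold to 179 higher and 232 lower, since fewer low genes were tested; leaving out 1 library gave 345 to 381 and 382 to 414. Of the 22 lists, 0 passed camera with an estimated correlation and 17 passed fry; leaving out 1 library gave 10 to 12. The 8mer difference ran from −0.278 (3′ UTRs of 200 to 3000 nt; the cause was not tested) to −0.125 and passed throughout. The difference for AGCACTT among 7-mers was −0.0623 without the length and GC correction (rank 67; the cause was not tested) and −0.0760 to −0.0710 on leaving out 1 library, with ranks from 60 to 102 (without control replicate 3) in place of 70. With the minimum of 5 CPM it ranked 30 of 15770 at −0.0751; the cause was not tested. Of 868 values of named genes under alternatives, 866 kept their direction and side of the threshold; both others are those of MT-ND4. No direction reversed. The filter removed no gene, so running without it says nothing. DESeq2 was not run for lists and sites, whose test uses voom values.

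Replicate numbers are shared between the groups, but deviations of same-numbered libraries correlated at −0.136, −0.052 and 0.103, which shows no clear pairing. With 3 libraries a group, these values cannot exclude that equal numbers mark a shared day or batch. With the replicate number as a block, 3381 genes rose and 3428 fell, 369 and 400 by at least 2-fold, and 10 lists passed; not every library correlated best with its own number. The least expressed genes are not in the table, and LIN28A rests on 14 control counts.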

Other observations

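The tests in this part of the Alu form, of HLA paralogs and of 6 interferon-induced genes, and the 4 gene lists of the next paragraphs, were chosen only after the results were seen. The camera p-values of these lists come from the same libraries that led to the choice. Their adjustment over 4 lists does not count that search, so they describe the lists and are not independent support.

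MHC class II genes were lower in overexpressing cells: all 11 measured fell (camera adjusted p over 4 lists = 3.7e-08; adjusted p = 0.028 with an estimated correlation). HLA-DRA fell 12.6-fold, the invariant chain gene CD74 fell 4.43-fold, from 302 ± 26.6 to 68.1 ± 1.79 CPM (SD, n = 3), and CIITA, the transactivator of class II genes, fell 3.68-fold. Of 17 complement genes, 9 fell and 3 rose (camera adjusted p = 0.00848; adjusted p = 0.0628 with an estimated correlation). C3 fell 7.73-fold, from 182 ± 10.7 to 23.5 ± 1.52 CPM (SD, n = 3), and C4A, C4B, CFB, C1R and C1S fell, while CD55, which protects cells from complement, rose 1.41-fold. C4A and C4B are near-identical, so their separate counts are uncertain.

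Genes of the actin and smooth muscle cytoskeleton rose in 14 of 17 cases and fell in 1 (camera adjusted p = 5.57e-07; adjusted p = 0.0672 with an estimated correlation). Besides TAGLN, FHL1 rose 3.44-fold, FLNC 3.01-fold and CNN1 2.96-fold; MYLK fell 1.22-fold. Of 27 published let-7 targets, 18 rose and 7 fell (camera adjusted p = 0.00106; adjusted p = 0.0394 with an estimated correlation). TRIM71 rose 4.81-fold, IGF2BP1 3.53-fold, ARID3A 3.26-fold, IGF2BP3 1.95-fold and MYC 1.65-fold, whereas ACVR1C fell 2.81-fold and HMGA2 1.32-fold.

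The lower level of genes with an 8mer site is one that direct pairing with miR-372-3p would give. Technical explanations were tested against it. With 3′ UTR length matched, the difference was −0.157; without genes holding the Alu form it was −0.140 and passed camera; and of 1268 other 8-mers made of the same bases, 0% had a difference of mean log2 fold change as low as that of AGCACTTA (−0.218, against −0.153 for the lowest). Length, Alu copies and base composition therefore do not account for all of it. Direct pairing may be the cause, which remains a hypothesis. Of the 3438 genes that fell, 221 carry an 8mer site, but 104 genes with that site rose. Since 26.2% of genes with no match also fell, the 221 are not a count of direct targets.

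The higher let-7 targets could reflect release from let-7, for example through LIN28A or by competition of the overexpressed microRNA for Argonaute proteins. Genes with the let-7 match CTACCTC in the 3′ UTR differed from the rest by 0.0223 ± 0.0152 in mean log2 fold change. This lay in the highest 14.96% of 7-mers, outside the 5% set before the test. The rank takes no account of how many genes hold a 7-mer: the highest, TCCGAAC, was in 122 genes and CTACCTC in 1374. No microRNA family examined reached that 5% (the closest, miR-221 and miR-222, lay at 5.81%). The rule set before the test counts a difference outside that 5% against release of let-7 sites. Because no family reached the 5%, that verdict is not relied on here. Whether let-7 sites in general were released is therefore not decided. Of 21 other microRNA families, 16 (76.2%) had a difference above 0, against 51% of all 7-mers. The family of miR-17 and miR-93 was left out because its site, GCACTTT, shares GCACTT with that of miR-372-3p; with it the share was 72.7% of 22, short of the 75% set before the test. Whether the sites of many microRNAs were released is therefore left open; differences were at most 0.0403, and the families are not independent of each other. LIN28B, which also blocks let-7, had 7.07, 57.1 and 56.5 CPM in control replicates 1 to 3 and 79.5 to 86.3 CPM in overexpressing cells, and did not pass (adjusted p = 0.11).

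The fall of MHC class II, complement and interferon genes was weighed against shared reads, direct pairing and a change of interferon response. Reads moved between HLA paralogs would leave CD74, CIITA and the sum of the 9 HLA class II genes unchanged, but CD74 had a log2 fold change of −2.15, CIITA of −1.88, and the sum went from 163 ± 3.68 to 36.5 ± 0.931 CPM (SD, n = 3). Of the 38 lower genes with a 3′ UTR, 21.1% held an 8mer or 7mer-m8 site, against 25.5% of other genes (Fisher's exact test, one-sided p = 0.791), and 0 held an 8mer, so direct pairing is not enriched among them. A weaker interferon response to the plasmid could not be decided. Of IFIT1, IFIT2, IFIT3, ISG15, MX1 and OAS1, 3 had a negative log2 fold change, counted without a p threshold, and IFIT2 rose 1.90-fold. The lower CIITA may link the class II genes, which was not tested.

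The 6 libraries can be split into 2 groups of 3 in 10 ways, too few for a share under 0.05. Every split but the real one puts libraries of both groups on each side, so the group difference adds to its spread. Low counts of changed genes in those splits follow from this, whatever made the groups differ. In each case 1 of the 10 splits, the real one, gave a result as large: 6761 genes changed against a highest other of 0, 747 genes changed at least 2-fold against 0, 10 gene lists against 6, and an 8mer difference of 0.138 in size against 0.0739. The 8mer difference still passed camera in 3 of the 9 other splits (adjusted p = 0.00585 to 0.0466), so its camera p alone does not set the real split apart. Those splits keep part of the group difference, so they do not show how often camera passes without one.

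In 12 cases a gene of at least 10 CPM differed at least 4-fold in 1 library from the other 2 of its group, which lay within 1.5-fold of each other. Besides LIN28B, IFI30 had 1.57 CPM in overexpression replicate 1 against 27.2 and 28.1 in the others, and the read-through gene NME1-NME2 had 0 in control replicate 3 against 77.2 and 58.3. Such differences are large for technical replicates, and how the reads were assigned to genes was not analysed here.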
